A study of Mus musculus with 15 samples.

How the data were processed

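RNA was sequenced from the cerebral cortex and the striatum of male C57Bl/6 mice aged 5 months, either wild type (WT) or lacking Slc1a4, the gene of the neutral amino acid transporter ASCT1 (KO). Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with the NEBNext Ultra RNA kit from 800 ng of total RNA. Per the series description, reads were single-end and 75 bp long and came from an Illumina NextSeq instrument. The 15 libraries form 4 groups: 4 of KO cortex, 4 of WT cortex, 3 of KO striatum and 4 of WT striatum. Nothing in the labels says that the replicates are separate animals, so the p-values measure only the spread between these samples.

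The submitters' processing notes name FastQC 0.11.5, cutadapt 1.1, TopHat2 2.1.1, HTSeq 0.6.0, DESeq2 1.12.4 and the genome build GRCm38, without the role or order of each tool. They state neither the strand setting of the counting nor the annotation release. Genes that overlap on opposite strands are therefore reported as uncertain. The deposited table holds 1 normalized signal value per gene and library, that is, read counts that the authors divided by 1 factor per library. Every column was a whole multiple of 1 step: 100% of the values lay within 0.001 of a whole count after division, and the largest deviation was 5.3e-05. Whole read counts could therefore be recovered from the deposited values. Libraries held 22990233 to 25697792 counted reads in striatum and 26791109 to 30276815 in cortex. At this depth replicates differed on average by far more than counting noise. The mean chi-square per gene was 7.12 to 77.4 between replicates of a group, over genes with at least 20 reads summed over the pair. For such genes on average the spread between samples outweighed counting noise. The mean does not speak for genes with few reads.

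The table has 26595 genes. Genes with a normalized count of at least 10 in at least 3 libraries were tested, which left 17030. Positions came from GENCODE M21 (GRCm38), which matched 99% of the genes by identifier. It also gave names to 7409 of the 7645 genes that had no symbol in the table.

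Differences were tested with limma 3.58.1 (R 4.3.3) on log2 of the normalized count plus 1, with a variance trend and a mean for each of the 4 groups fitted to all 15 libraries (11 residual degrees of freedom). The 5 comparisons were KO against WT in cortex, KO against WT in striatum, the difference between those effects, striatum against cortex in WT, and striatum against cortex in KO. A gene was called when its limma p, adjusted by the Benjamini-Hochberg method over all genes tested, was below 0.05. Log2 fold changes are given with their standard error (SE), normalized counts with their standard deviation (SD), and intervals at 95%. Single comparisons of Slc1a4 also carry a two-sided exact permutation test.

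A total of 31 gene lists was fixed for cell types, amino acid and lipid metabolism, synaptic receptors, stress and immune responses, ribosomal and respiratory genes, and genes next to Slc1a4 on chromosome 11. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 31 lists within a comparison. Camera asks whether a list moves relative to the other genes. Fry, which asks whether the genes of a list move one way on balance, and camera with an estimated correlation were run as alternatives. Scores per library are the mean log2 deviation of a list's genes from their mean in that tissue.

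Genes were named by a fixed rule: up to 12 higher and 12 lower genes with the largest change among those called, with a mean normalized count of at least 20 and no overlap between the groups, leaving out predicted genes. Where fewer than 5 genes passed, the 10 with the smallest p were also taken and are given as not past the test. From each list came up to 4 called members, or the 2 with the smallest p as values only. Some genes that this rule takes are not reported here. The groups, comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives were other pseudocounts, filters and scalings, edgeR 4.0.16, DESeq2 1.42.0 and voom on the recovered reads, sample weights, robust variances, single tissues or genotypes, the replicate number as a block, and each library left out in turn. The removal of trends with transcript length and GC content, a fit without the striatum libraries rich in choroid plexus transcripts, and the list tests with each library left out were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

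The test was checked on simulated counts with the real means and depths and 1 dispersion per gene, the same in all libraries. The 200 changed genes were drawn from those with higher mean counts, so the recovery does not speak for genes with few reads. In the simulated cortex comparison (16857 genes) it recovered 61.2% of the genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, with 3 false calls. In the simulated striatum comparison (16876 genes) it recovered 56.7%, 88.1% and 98.5%, with 9 false calls. With DESeq2 the false calls were 27 in cortex and 38 in striatum. In the simulated comparison of WT striatum and cortex (16766 genes) limma recovered 67.2%, 88.1% and 100%, with 9 false calls. The simulated spread was the same in both tissues, whereas real striatum replicates differed more than cortex replicates. These false calls therefore do not show how the tests perform on the real striatum libraries. Camera, tested on 30 simulated lists of 30 genes with 1 list raised, called that list and 0 others, with the preset and with an estimated correlation. The simulated genes varied independently, whereas the estimated correlation reached 0.91 for choroid plexus markers in KO against WT cortex. The check therefore does not show how the preset correlation performs on lists of correlated genes.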

Results

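Gene expression was measured by RNA sequencing in cerebral cortex and striatum of WT mice and of mice lacking Slc1a4, which encodes the neutral amino acid transporter ASCT1. There were 4 libraries of KO cortex (28114119 to 30276815 counted reads), 4 of WT cortex (26791109 to 29342263 reads), 3 of KO striatum (23260155 to 24006391 reads) and 4 of WT striatum (22990233 to 25697792 reads). The series asks how the transcriptomes of the 2 tissues differ and what the loss of ASCT1 changes in each.

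Slc1a4 (ENSMUSG00000020142, GRCm38 chromosome 11, positions 20302180 to 20332713, minus strand) was low in every KO library and high in every WT library. In cortex it stood at 265 ± 28.7 normalized counts in KO (SD, n = 4) and 1624 ± 127 in WT (SD, n = 4), so that 16.3% of the WT level remained. In striatum it stood at 271 ± 99.3 in KO (SD, n = 3) and 1533 ± 217 in WT (SD, n = 4), or 17.7% of the WT level. The fall was -2.61 on the log2 scale in cortex (SE 0.19, limma adjusted p = 1.2e-05) and -2.56 in striatum (SE 0.20, limma adjusted p = 2.3e-05). A two-sided exact permutation test gave p = 0.029 in each tissue, the smallest value that these group sizes allow. KO cortex libraries lay between 249 and 308 and WT cortex libraries between 1494 and 1797. KO striatum libraries lay between 158 and 344 and WT striatum libraries between 1237 and 1726. The labels do not give the deleted part of the gene, so the remaining reads cannot be assigned to intact or altered transcripts. Fitted on the striatum libraries alone, the striatal fall was still -2.56 but its limma adjusted p was 0.088. The adjusted p ranged from 2.8e-32 to 0.088 over the alternatives.

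**Figure D1:**
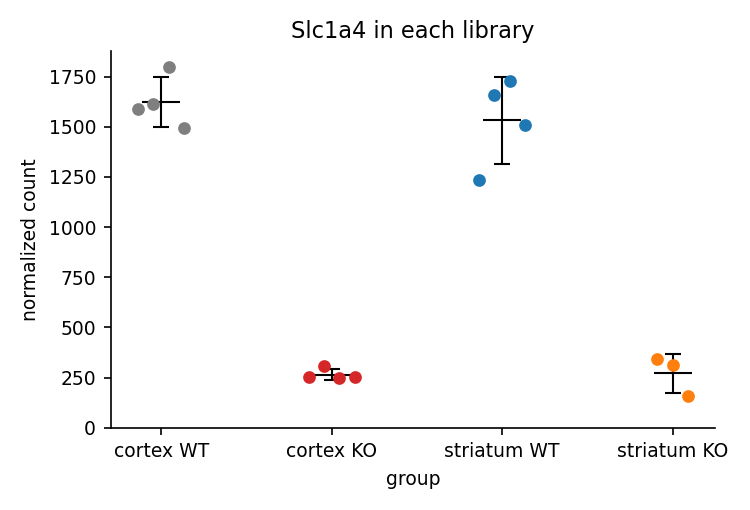
Slc1a4 in each library, in normalized counts, by group (cortex WT n = 4, cortex KO n = 4, striatum WT n = 4, striatum KO n = 3). Points are libraries, horizontal bars are means and whiskers are SD; every KO library lies at or below 344 and every WT library at or above 1237.

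The comparison of KO and WT cortex asked what the loss of the transporter changes in cortical tissue. Slc1a4 was the 1 gene called among 17030 tested, with 1 gene lower and 0 higher in KO. The genes next in order of p did not pass limma's test (adjusted p = 1) and are given as values. Among them were 2 enzymes of cholesterol synthesis, Mvk at 335 ± 3.18 in KO against 398 ± 5.49 in WT and Msmo1 at 1896 ± 67 against 2285 ± 64.3 (SD, n = 4 each). A pair of genes of acetylcholine neurons, Chat (choline acetyltransferase) and Slc18a3 (the vesicular acetylcholine transporter), stood at 10 ± 4.99 against 37.9 ± 25 and at 5.88 ± 2.52 against 12.9 ± 2.81. The Slc18a3 gene lies within the Chat gene, on the same strand, so the split of their reads is uncertain. Rnd2 stood at 1422 ± 49.4 against 1718 ± 92.3, and C8g at 9.35 ± 1.90 against 19.7 ± 4.78. Values were higher in KO for Dusp4, a phosphatase of MAP kinases (310 ± 22.4 against 208 ± 26.5), Thsd4 (327 ± 148 against 149 ± 16.4), Slc9a2, a sodium-hydrogen exchanger (166 ± 71.8 against 82.8 ± 5.41), and Cfap221, a ciliary gene (7.25 ± 1.80 against 1.69 ± 0.991). At an unadjusted limma p below 0.05 there were 427 genes, where 852 would be expected by chance. The fit shares 1 variance per gene between the tissues. Replicates differed less in cortex (mean chi-square per gene 7.12 to 19.3) than in striatum (8.99 to 77.4). This sharing can make p-values too large in cortex and too small in striatum. Fitted on the cortex libraries alone, with fewer residual degrees of freedom, limma also called 1 gene, the same one. Removing the sharing thus added no calls, but a low count in cortex does not show the absence of an effect. The count was 1 with edgeR, 1 with voom, 2 with sample weights and 3 with DESeq2. Weights added Cfap221 (adjusted p = 0.017) and DESeq2 added Chat (adjusted p = 0.042) and Thsd4 (adjusted p = 0.044).

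Across cortex, several fixed lists differed by small amounts at the preset correlation, and no member of any list passed the test over all genes. Cholesterol synthesis genes had log2 fold changes below 0 for 23 of 25 tested members (median -0.145, camera adjusted p = 7.4e-14, adjusted p = 0.14 with an estimated correlation). Of these, 2 members, Mvk and Msmo1, were lower when adjusted over the list alone. Nuclear-encoded respiratory chain subunits had log2 fold changes below 0 for 79 of 83 members (median -0.117, camera adjusted p = 7.3e-22, adjusted p = 0.58 with an estimated correlation). Values of the ATP synthase subunit Atp5k were 1037 ± 56.5 in KO and 1229 ± 89.5 in WT, and those of the cytochrome oxidase subunit Cox7a2 were 2062 ± 138 and 2408 ± 123. Cytosolic ribosomal protein genes had log2 fold changes below 0 for 72 of 77 (median -0.0722, camera adjusted p = 5.2e-13, adjusted p = 0.58 with an estimated correlation), with Rpl37 at 2277 ± 122 against 2513 ± 230. The ribosomal median was -0.0256 without WT replicate 7 and -0.122 without WT replicate 8. In these libraries the fold changes of cortex also rose with transcript length across 11664 genes (Spearman's rank correlation 0.45, across genes, which are not independent replicates), and ribosomal and respiratory transcripts are short. With trends in transcript length and GC content removed, the ribosomal median was -0.00105 (camera adjusted p = 0.79) and the respiratory median -0.0278 (camera adjusted p = 5.2e-07, adjusted p = 0.55 with an estimated correlation).

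Lists of markers of cells outside the cortical sheet, and the separate list of reactive gliosis genes, were called between the cortex groups at the preset correlation. They were not called with an estimated one. Choroid plexus markers had log2 fold changes above 0 in KO cortex for 20 of 20 members (median 1.25, camera adjusted p = 1.9e-07, adjusted p = 0.58 with an estimated correlation), among them the prolactin receptor Prlr (123 ± 40.3 against 45 ± 18.1). Ependymal markers had log2 fold changes above 0 for 18 of 19 members (median 0.683, or 0.352 without WT replicate 7, camera adjusted p = 4.1e-09, adjusted p = 0.58 with an estimated correlation), among them Spag17 (19.8 ± 3.48 against 6.26 ± 3.19) and Tmem212 (22.8 ± 2.65 against 9.31 ± 5.87). Meningeal and fibroblast markers had log2 fold changes above 0 for 21 of 22 (median 0.282, camera adjusted p = 0.00042, adjusted p = 0.58 with an estimated correlation). This call ended without KO replicate 2 (median 0.128) or WT replicate 8 (0.159), and the median was 0.434 without KO replicate 4 and 0.467 without WT replicate 7. Reactive gliosis genes had log2 fold changes above 0 for 18 of 25 (median 0.222, camera adjusted p = 0.0037, adjusted p = 0.58 with an estimated correlation), a call that ended without KO replicate 2 (median 0.0262) or WT replicate 8 (0.167). In that list, values of Lcn2 (lipocalin) were 62.6 ± 54.9 against 14 ± 11.1, and values of the oncostatin M receptor gene Osmr were 205 ± 137 against 105 ± 6.54, with KO replicate 2 far above the others. Striatal projection neuron markers had log2 fold changes below 0 for 30 of 30 members (median -0.339, camera adjusted p = 1.4e-06, adjusted p = 0.58 with an estimated correlation), with Gpr6 at 51.6 ± 19.1 against 99.2 ± 59. Their median was -0.153 without WT replicate 8, -0.178 without WT replicate 5 and -0.577 without WT replicate 7.

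Activity-regulated immediate early genes had log2 fold changes above 0 for 27 of 28 members in KO cortex (median 0.253, camera adjusted p = 2.6e-05, adjusted p = 0.58 with an estimated correlation). Heat shock and ER chaperones had log2 fold changes below 0 for 23 of 30 (median -0.0774, camera adjusted p = 5.4e-05, adjusted p = 0.58 with an estimated correlation), with the chaperone Hspa5 at 7785 ± 595 against 9283 ± 1053. The immediate early median was 0.102 without WT replicate 5, 0.163 without KO replicate 3 and 0.407 without WT replicate 7, and the chaperone median -0.0486 without WT replicate 7 and -0.119 without WT replicate 6. Serine and glycine metabolism, the pathway nearest to the substrates of ASCT1, had log2 fold changes below 0 for 16 of 20 members (median -0.0564, camera adjusted p = 0.010, adjusted p = 0.14 with an estimated correlation), and not called without WT replicate 6 (median -0.0548, camera adjusted p = 0.057). Its member with the smallest p was Gamt, an enzyme of creatine synthesis, at 132 ± 11 against 166 ± 19.8. Smaller calls at the preset correlation were endothelial and pericyte markers (median 0.0606, adjusted p = 0.028), ATF4 targets of the integrated stress response (0.0382, adjusted p = 0.034), astrocyte markers (-0.0846, adjusted p = 0.031), interneuron markers (-0.0737, adjusted p = 0.031, with Chat and Slc18a3 lower when adjusted over the list alone), microglia markers (-0.0466, adjusted p = 0.038) and interferon response genes (-0.0471, adjusted p = 0.049). With an estimated correlation these 6 had an adjusted p of 0.59 or 0.64. They kept their call in 11, 11, 12, 11, 10 and 6 of the 15 fits that left out 1 library, and without WT replicate 7 the astrocyte median turned to 0.0052 and the microglia median to 0.012. The endothelial median was 0.00188 without WT replicate 6, 0.0223 without WT replicate 8, 0.0295 without KO replicate 2, 0.112 without KO replicate 1 and 0.17 without WT replicate 7. The interferon median was -0.0815 without WT replicate 7, -0.0869 without KO replicate 2 and -0.137 without WT replicate 8. The microglia median was -0.0225 without KO replicate 3, -0.026 without KO replicate 1, -0.0737 without KO replicate 4 and -0.0741 without WT replicate 8. The ATF4 median was 0.0196 without KO replicate 2, the astrocyte median -0.0422 without KO replicate 3 and the interneuron median -0.0355 without KO replicate 4. Circadian and glucocorticoid-responsive genes were not called (median -0.0364, adjusted p = 0.13), although the clock-controlled factor Dbp stood at 1759 ± 308 against 2478 ± 234. Glutamate receptors were not called either (median 0.0271, adjusted p = 0.094), with Grin2b at 17777 ± 386 against 15341 ± 749 and Gria1 at 10213 ± 1579 against 8303 ± 307. In all, 17 of 31 lists were called, 7 up and 10 down. Camera with an estimated correlation called 0 (2 at an unadjusted p below 0.05), and so did fry (2 at an unadjusted p below 0.05).

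The comparison of KO and WT striatum asked the same question in the other tissue. Apart from Slc1a4, 12 genes were called and all were higher in KO. The largest rises were in Lrg1, a secreted glycoprotein (45.9 ± 17.2 in KO, SD, n = 3, against 5.44 ± 4.03 in WT, SD, n = 4), Smoc2, a secreted matrix protein (99.9 ± 54.7 against 15 ± 10.4), Rtn4rl2, a receptor of the Nogo receptor family (138 ± 31.3 against 31.4 ± 21.9), and Neurod2, a transcription factor of cortical excitatory neurons (309 ± 151 against 62.3 ± 34.6). On the log2 scale these were 2.97 (SE 0.47), 2.69 (SE 0.40), 2.34 (SE 0.37) and 2.30 (SE 0.38). Scube1, a secreted and cell-surface protein with EGF-like domains, had the smallest p of the 12 (561 ± 147 against 150 ± 22.4, log2 fold change 1.87, SE 0.14, limma adjusted p = 2.3e-05).

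Further rises were in Nwd2 (739 ± 384 against 185 ± 52.6, log2 fold change 1.92), Ptgs2, the inducible cyclooxygenase (196 ± 47.6 against 60.1 ± 15.7, 1.70), and the neuronal pentraxin receptor Nptxr (6424 ± 1069 against 3207 ± 769, 1.02). Slit2, an axon guidance ligand, stood at 1068 ± 169 against 614 ± 100 (0.80), Ptchd2 at 747 ± 77.3 against 440 ± 79.3 (0.78), and Tnks1bp1, a tankyrase-binding protein, at 1121 ± 105 against 830 ± 46.5 (0.43). The predicted gene Gm9954 also passed (131 ± 18.7 against 58.3 ± 9.13). It falls outside the naming rule, was named after its values were seen, and overlaps Nwd2 on the opposite strand on chromosome 5, so reads of that pair cannot be told apart. The limma adjusted p of the 12 lay between 2.3e-05 and 0.030. All 12 genes had higher mean counts in cortex of either genotype than in WT striatum. In KO striatum 10 of the 12 were still called lower than in KO cortex, the exceptions being Lrg1 (limma adjusted p = 0.395) and Slit2 (limma adjusted p = 0.35). The comparisons share the KO striatum libraries, and in 50 simulations with no difference between the striatum groups 0 to 6 of the top 12 genes were called that way (mean 2.26). The simulated noise was independent between genes, whereas marker genes of the real striatum libraries varied together. The simulated range can therefore be too low for these samples.

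The striatal count depended on single libraries and on the test. It was 517 genes without KO replicate 4 (59.4% of them higher in KO), 187 without WT replicate 8 (49.7% higher), 21 without WT replicate 7 and 4 without WT replicate 6. Without a cortex library, which contributes only to the variance, it was 11 (KO replicate 2), 11 (WT replicate 7), 7 (KO replicate 1), 7 (KO replicate 3), 6 (KO replicate 4), 6 (WT replicate 5), 5 (WT replicate 6) or 5 (WT replicate 8). Slc1a4, Scube1, Nwd2 and Gm9954 stayed called in each of the 15 fits that left out 1 library, Ptgs2 in 13, Smoc2 in 11, Lrg1 in 8, Ptchd2 in 6, Nptxr, Rtn4rl2 and Slit2 in 5, Neurod2 in 4 and Tnks1bp1 in 2. With limma on the striatum libraries alone the count was 0, with 1140 genes at an unadjusted p below 0.05. It was 3 with voom, 17 with edgeR, 22 with no filter, 35 with sample weights and 333 with DESeq2. With all libraries there were 2598 genes at an unadjusted limma p below 0.05 against 852 expected by chance. The variance shared with the less variable cortex libraries can make that count too large.

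**Figure D2:**
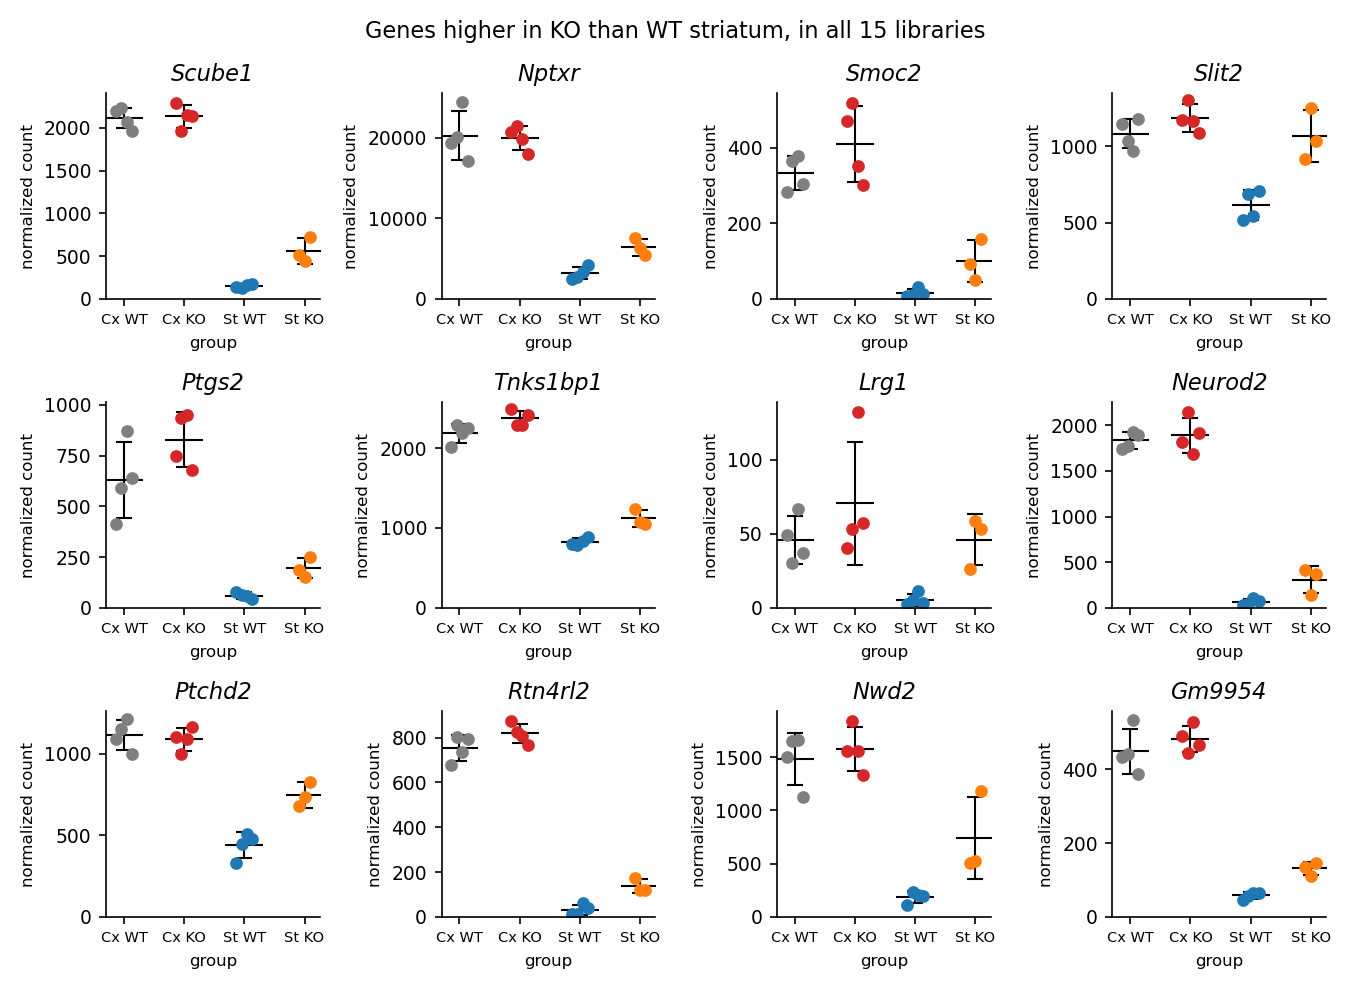
The 12 genes higher in KO than WT striatum in all 15 libraries, in normalized counts (Cx, cortex; St, striatum). Points are libraries, horizontal bars are means and whiskers are SD; each gene's KO striatum libraries lie above its WT striatum libraries, and cortex means lie above those of WT striatum.

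The lists of regional neuron markers had medians of opposite sign in KO striatum. Striatal projection neuron markers had log2 fold changes below 0 for 30 of 30 members (median -0.816, or -0.405 without KO replicate 4, camera adjusted p = 7.8e-12, adjusted p = 0.43 with an estimated correlation). None was called over all genes, and 13 were lower when adjusted over the list alone, with values for Arpp19 of 8371 ± 2967 against 14346 ± 3517 and for Arpp21 of 16047 ± 6631 against 28699 ± 8527. Cortical excitatory neuron markers had log2 fold changes above 0 for 16 of 25 (median 0.428, camera adjusted p = 0.00066, adjusted p = 0.43 with an estimated correlation, fry adjusted p = 0.048). Their median was 0.264 without WT replicate 5, 0.272 without KO replicate 4 and 0.648 without WT replicate 8. Neurod2 was the 1 member called over all genes, and 10 members were higher when adjusted over the list alone. The libraries of a group differed in these scores. KO replicate 4 had a striatal marker score of -1.19 against -0.0891 and -0.093 in the other KO libraries, and WT replicate 8 had -0.268 against 0.296 to 0.782 in the other WT libraries. Scores of thalamic, septal and pallidal neighbour markers were 1.08 and 0.778 in these 2 libraries and -0.959 to 0.0839 in the others. Choroid plexus scores were 2.73 in KO replicate 4 and 3.17 in WT replicate 5, and -1.97 to -0.549 in the other striatum libraries. Without those 2 libraries, the striatal comparison called 344 genes, 235 higher and 109 lower, including the 13 called with all libraries.

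**Figure D3:**
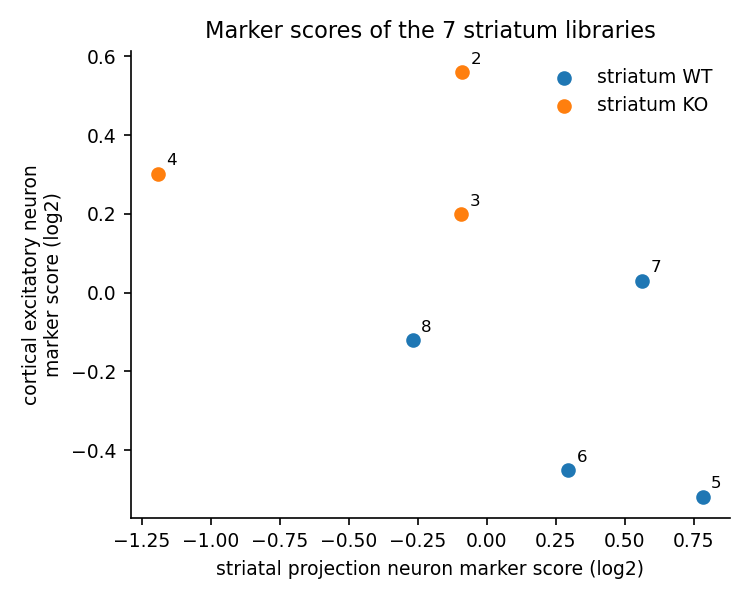
Scores of the striatal projection neuron list (horizontal axis) and the cortical excitatory neuron list (vertical axis) in the 7 striatum libraries, in log2 units relative to the striatum mean, labelled by replicate number. KO replicate 4 lies at -1.19 on the striatal score, and the 3 KO libraries lie at 0.199 to 0.56 on the cortical score.

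Lists of energy and protein synthesis genes were called as lower in KO striatum at the preset correlation and not with an estimated one. Nuclear-encoded respiratory chain subunits had log2 fold changes below 0 for 83 of 83 members (median -0.185, or -0.0953 without KO replicate 3, camera adjusted p = 9.1e-21, adjusted p = 0.43 with an estimated correlation), with Cox5b at 2447 ± 310 against 3001 ± 226. Cytosolic ribosomal protein genes had log2 fold changes below 0 for 75 of 77 (median -0.156, camera adjusted p = 1.9e-17, adjusted p = 0.43 with an estimated correlation), with Rpl31 at 3041 ± 246 against 3680 ± 209. Mitochondrially encoded genes had log2 fold changes below 0 for 12 of 12 (median -0.29, camera adjusted p = 1.9e-06, adjusted p = 0.43 with an estimated correlation, fry adjusted p = 0.041), with the complex I genes ND3 at 164 ± 11.8 against 250 ± 28.2 and ND4 at 99252 ± 8091 against 122170 ± 6441. ND4 turned to 0.01 on the log2 scale after quantile normalization. None of these members passed the test over all genes or over the list alone. Fold changes rose with transcript length here as well (Spearman's rank correlation 0.30 across 11664 genes). With the trend removed, the medians were -0.104 for respiratory and -0.0622 for ribosomal genes.

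Serine and glycine metabolism had log2 fold changes below 0 in KO striatum for 16 of 20 members (median -0.189, or -0.123 without KO replicate 3, camera adjusted p = 0.0030, adjusted p = 0.12 with an estimated correlation, fry adjusted p = 0.0072). When adjusted over the list alone, 3 members were lower, and the smallest p values belonged to Gamt (238 ± 54.5 against 352 ± 29.9) and Cth, an enzyme of cysteine synthesis (85.5 ± 12.3 against 124 ± 17.3). ATF4 targets of the integrated stress response had log2 fold changes above 0 for 27 of 36 members (median 0.113, camera adjusted p = 0.0036, adjusted p = 0.47 with an estimated correlation). When adjusted over the list alone 1 member was higher, and the cysteine tRNA ligase Cars stood at 825 ± 75 against 643 ± 40.6. The ATF4 call ended without KO replicate 4 (median 0.0877, camera adjusted p = 0.16), and the median was 0.0696 without WT replicate 6. Other amino acid transporters did not move as a group (median 0.0839, camera adjusted p = 0.18), with the cationic amino acid transporters Slc7a1 at 1404 ± 127 against 1101 ± 159 and Slc7a3 at 401 ± 85.9 against 201 ± 100.2. One-carbon and folate metabolism (median -0.000353, mean 0.0411, tested as down, adjusted p = 0.93) and sphingolipid and phosphatidylserine synthesis (median -0.0242, adjusted p = 0.40) were not called. The corresponding medians in cortex were 0.0271 for transporters, 0.0106 for one-carbon metabolism and 0.0233 for sphingolipid synthesis, with camera adjusted p of 0.29, 0.40 and 0.73. The sphingolipid list in cortex had a mean of -0.0135 and was tested as down against its positive median.

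Microglia markers had log2 fold changes below 0 in KO striatum for 23 of 29 members (median -0.213, or -0.123 without KO replicate 3, camera adjusted p = 1.8e-06, adjusted p = 0.43 with an estimated correlation). Over the list alone 7 were lower, and P2ry12 stood at 1067 ± 82.2 against 1401 ± 116 and Selplg at 576 ± 102 against 732 ± 41.5. Circadian and glucocorticoid-responsive genes had log2 fold changes below 0 for 22 of 28 (median -0.212, camera adjusted p = 0.00012, adjusted p = 0.43 with an estimated correlation). Over the list alone 3 were lower, and the clock-controlled factor Dbp stood at 2247 ± 361 against 3717 ± 623 and Tef, another, at 8386 ± 1143 against 10910 ± 365. Heat shock and ER chaperones had log2 fold changes below 0 for 29 of 30 (median -0.15, camera adjusted p = 9.9e-07, adjusted p = 0.43 with an estimated correlation). Hspa1b, whose reads may be shared with its near-identical copy Hspa1a, stood at 101 ± 41.2 against 219 ± 96.9 and Hspa5 at 9294 ± 719 against 12076 ± 1858. Oligodendrocyte and myelin genes had log2 fold changes below 0 for 28 of 30 (median -0.183, camera adjusted p = 0.0098, adjusted p = 0.87 with an estimated correlation). Their direction rested on KO replicate 3, without which the median was 0.0404. The call also ended without KO replicate 2 (-0.157) or WT replicate 8 (-0.146), and the median was -0.472 without KO replicate 4. Cholesterol synthesis genes had log2 fold changes above 0 for 17 of 25 (median 0.078, camera adjusted p = 0.015, adjusted p = 0.61 with an estimated correlation), with 4 higher over the list alone and squalene epoxidase (Sqle) at 1464 ± 96.3 against 1177 ± 112. This call ended without KO replicate 2 (median 0.0585) or KO replicate 4 (0.066), and the median was 0.172 without KO replicate 3. Reactive gliosis genes had log2 fold changes above 0 for 19 of 25 (median 0.257, camera adjusted p = 0.031, adjusted p = 0.77 with an estimated correlation), with 2 higher over the list alone and Lcn2 at 84.2 ± 45.2 against 5.34 ± 4.31. That call ended without KO replicate 2 (0.147), KO replicate 4 (0.171), WT replicate 7 (0.194), WT replicate 8 (0.251) or cortical WT replicate 6 (0.194). Ependymal markers had log2 fold changes above 0 for 19 of 19 (median 0.418, camera adjusted p = 0.021, adjusted p = 0.86 with an estimated correlation), a call that ended without WT replicate 8 (0.103), KO replicate 4 (0.166) or KO replicate 3 (0.355). Their median was 0.663 without WT replicate 5 and 0.773 without KO replicate 2.

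The remaining lists were not called in striatum. Glutamate receptors had a median of -0.0496 but a mean of 0.0832 and were tested as up (camera adjusted p = 0.93), with Grm2 at 370 ± 160 against 178 ± 94.7. Endothelial markers had a median of -0.0822 (adjusted p = 0.51), with von Willebrand factor (Vwf) at 879 ± 162 against 479 ± 59.3. Medians were 0.269 for choroid plexus, 0.0859 for meningeal, 0.0408 for blood, 0.271 for thalamic, septal and pallidal neighbour, -0.0592 for interneuron, -0.0844 for astrocyte and -0.0398 for oligodendrocyte precursor markers. The means of the astrocyte (0.00341) and precursor lists (0.00577) had the opposite sign to their medians, and both were tested as down. Medians were 0.0365 for GABA machinery, -0.0314 for the postsynaptic scaffold, -0.0992 for interferon response and -0.0477 for chromosome 11 neighbours. Immediate early genes had a median of 0.0101 (adjusted p = 0.099), with Ptgs2 called over all genes and 3 members higher when adjusted over the list alone. In cortex the uncalled medians were 0.0781 for neighbour regions, 0.0421 for blood, 0.027 for oligodendrocytes, 0.0247 for their precursors, 0.0106 for cortical neurons, 0.00265 for GABA machinery, 0.0142 for the scaffold, 0.0322 for chromosome 11 neighbours and -0.0226 for mitochondrially encoded genes. In all, 14 of 31 lists were called in striatum, 5 up and 9 down. Camera with an estimated correlation called 0 (2 at an unadjusted p below 0.05), and fry called 3 (9 at an unadjusted p below 0.05).

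**Figure D4:**
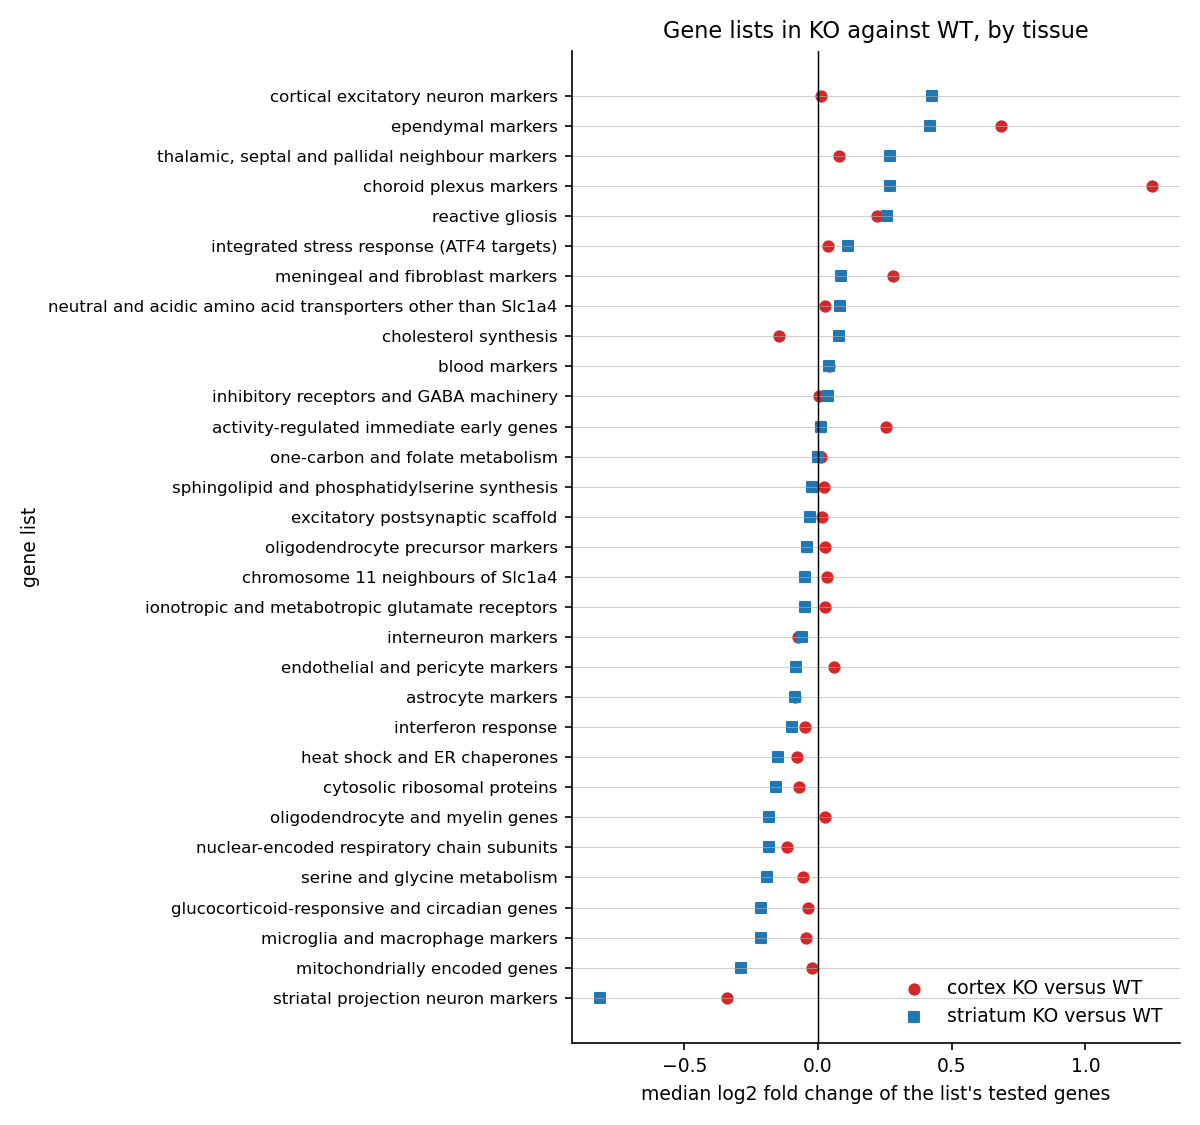
Median log2 fold change (KO against WT) of the tested genes of each of the 31 lists, in cortex (circles) and striatum (squares). Striatal projection neuron markers lie at -0.339 in cortex and -0.816 in striatum, and choroid plexus markers at 1.25 in cortex and 0.269 in striatum.

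The difference between the striatal and the cortical effect of the knockout was tested directly. Scube1 was the 1 gene called: its KO effect was larger in striatum by 1.86 on the log2 scale (SE 0.19, limma adjusted p = 0.0017). In cortex Scube1 stood at 2135 normalized counts in KO and 2116 in WT. For Slc1a4 the difference was 0.05 (SE 0.28, limma adjusted p = 1, 95% interval -0.56 to 0.66), and it turned negative without striatal KO replicate 2 (-0.16), KO replicate 3 (-0.09) or WT replicate 5 (-0.05) and with quantile normalization (-0.01). At an unadjusted limma p below 0.05 there were 834 genes against 852 expected by chance. The count was 1 with edgeR and voom, 4 with sample weights and 15 with DESeq2, and 8 without striatal KO replicate 4, 3 without striatal WT replicate 7, 2 without striatal KO replicate 2 and 2 without striatal KO replicate 3. With the replicate number as a fixed block limma called 0 genes (868 at an unadjusted p below 0.05), where Scube1 had an adjusted p of 0.13, within a range of 1.6e-16 to 0.13 over the alternatives. Among lists, 13 of 31 were called at the preset correlation, 2 up and 11 down, and 0 with an estimated correlation (3 at an unadjusted p below 0.05) or with fry (4 at an unadjusted p below 0.05). The call with the smallest p was cholesterol synthesis (median difference 0.229, camera adjusted p = 5.6e-12, adjusted p = 0.26 with an estimated correlation). Its median was 0.078 in striatum and -0.145 in cortex.

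The comparison of WT striatum and WT cortex described the difference between the samples of the 2 regions. Called genes numbered 4232 higher and 4369 lower in striatum, of which 1261 and 1272 differed at least 2-fold. Striatal projection neuron markers had 29 of 30 members called higher (median 3.07, camera adjusted p = 2.6e-15, adjusted p = 0.41 with an estimated correlation). They included the dopamine receptor Drd2 at 2890 ± 915 against 177 ± 146 (SD, n = 4 each), the adenosine receptor Adora2a at 5916 ± 2226 against 340 ± 273, and the developmental transcription factors Six3 (2381 ± 391 against 44.7 ± 34) and Isl1 (501 ± 24 against 12.4 ± 12.3). Cortical excitatory neuron markers had 19 of 25 members called lower and 3 called higher (median -2.29, camera adjusted p = 1.1e-07, adjusted p = 0.16 with an estimated correlation), with Emx1 at 11.8 ± 5.24 in striatum against 535 ± 89.8 in cortex, Neurod2 at 62.3 ± 34.6 against 1835 ± 90.2 and Neurod6 at 83.5 ± 53.4 against 1766 ± 168.

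Among the genes with the largest rises in striatum were the cholecystokinin receptor Cckar (106 ± 17.4 against 0.235 ± 0.471), Lhx8, a factor of cholinergic neurons (312 ± 41.2 against 5.05 ± 5.71), Dlk1 (999 ± 537 against 15.4 ± 10.4), the orphan receptor Gpr101 (859 ± 451 against 14.3 ± 8.40), Dgkk (476 ± 267 against 7.09 ± 1.74) and Frem3 (130 ± 62.3 against 1.39 ± 1.18). Six3os1 (676 ± 91.4 against 19.3 ± 16.5) overlaps Six3 on the opposite strand, so that the reads of that pair are uncertain. Shox2 (884 ± 517 against 3.60 ± 1.76) marks thalamus, and the hypothalamic neuropeptide genes Pmch and Hcrt stood at 2357 ± 3504 against 10.7 ± 9.58 and 353 ± 535 against 1.20 ± 0.902. Their striatal means rested largely on WT replicate 8, with 7575 for Pmch and 1152 for Hcrt, and voom did not call them (adjusted p of 0.23 and 0.12). The genes with the largest falls included Igfn1 (17.7 ± 25.4 against 1286 ± 231), the netrin Ntn5 (6.54 ± 6.75 against 325 ± 43.1), Ovol2 (2.44 ± 1.43 against 200 ± 22.9), the T-cell receptor constant segment Trbc2 (3.57 ± 1.97 against 231 ± 35), Dkkl1 (10.8 ± 4.03 against 500 ± 35), Serpinb8 (15.8 ± 12.3 against 554 ± 73.8) and Adam33 (10.1 ± 5.95 against 390 ± 57). Krt80 (3.10 ± 3.61 against 128 ± 49.8), Mylk3 (3.56 ± 2.29 against 172 ± 23.4) and Cdsn (0.545 ± 0.63 against 60.3 ± 4.96) followed. Trbc2 has a close paralog, so its reads are uncertain.

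Glial, neighbouring and synaptic groups differed between the samples of the 2 tissues as well. Markers of choroid plexus and of neighbour regions were uneven among WT striatum libraries. The choroid plexus gene Ttr ranged from 682 (replicate 6) to 130616 (replicate 5), and neighbour-region scores from -0.959 (replicate 5) to 0.778 (replicate 8). For those lists the make-up of the samples cannot be told apart from a difference between striatum and cortex. Myelin genes had 29 of 30 members called higher in WT striatum (median 1.34, camera adjusted p = 1.0e-11, adjusted p = 0.41 with an estimated correlation), with Mobp at 29884 ± 6617 against 10122 ± 3495. Oligodendrocyte precursor markers had 11 of 15 members called higher and 2 called lower (median 0.676, camera adjusted p = 0.00065, adjusted p = 0.41 with an estimated correlation), with Lhfpl3 at 1924 ± 343 against 567 ± 54.8. Microglia markers had 18 of 29 members called higher and 3 called lower (median 0.331, camera adjusted p = 0.00078, adjusted p = 0.55 with an estimated correlation). Ependymal markers had 19 of 19 members called higher (median 1.66, camera adjusted p = 7.2e-06, adjusted p = 0.41 with an estimated correlation). Choroid plexus markers had 10 of 20 members called higher (median 2.66, camera adjusted p = 0.0028, adjusted p = 0.66 with an estimated correlation), with Prlr at 971 ± 982 against 45 ± 18.1. Without striatal WT replicate 5, the library with the choroid plexus score of 3.17, that median was 1.49 (camera adjusted p = 0.028). Neighbour-region markers had 18 of 24 members called higher and 1 called lower (median 2.08, camera adjusted p = 0.00011, adjusted p = 0.41 with an estimated correlation), with the thalamic factor Gbx2 at 76.9 ± 53.2 against 1.45 ± 0.967. Interneuron markers had 14 of 25 members called higher and 4 called lower (median 0.76, camera adjusted p = 0.014, adjusted p = 0.55 with an estimated correlation), with the choline transporter Slc5a7 at 1781 ± 263 against 63.7 ± 33.2 and Vip at 48.4 ± 13.7 against 1250 ± 189. GABA machinery had 12 of 25 members called higher and 5 called lower (median 0.273, camera adjusted p = 0.028, adjusted p = 0.55 with an estimated correlation), with Gad2 at 19575 ± 3371 against 5139 ± 291 and the vesicular transporter Slc32a1 at 6719 ± 485 against 2107 ± 136. It was not called without striatal WT replicate 6 (median 0.271, camera adjusted p = 0.064).

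The excitatory postsynaptic scaffold had 17 of 27 members called lower in WT striatum and 2 called higher (median -0.457, camera adjusted p = 0.00074, adjusted p = 0.41 with an estimated correlation), with Shank1 at 4985 ± 1652 against 18546 ± 2208 and Camk2a at 34488 ± 4634 against 96890 ± 13493. Immediate early genes had 18 of 28 members called lower and 1 called higher (median -1.03, camera adjusted p = 5.3e-05, adjusted p = 0.41 with an estimated correlation), with Bdnf at 102 ± 56.6 against 803 ± 92. Cholesterol synthesis genes had 16 of 25 members called lower (median -0.367, camera adjusted p = 0.00017, adjusted p = 0.41 with an estimated correlation). Glutamate receptors were not called as a list (median 0.0445 but mean -0.0129, tested as down, adjusted p = 0.98), with 8 members called higher and 7 lower, including Grm2 (178 ± 94.7 against 1191 ± 117) and Grin2a (4145 ± 190 against 9931 ± 508). Meningeal markers were not called (median -0.36, adjusted p = 0.19), although Nov fell (194 ± 75.2 against 2281 ± 359). Ribosomal genes (median 0.221, 42 of 77 called higher), respiratory subunits (0.172, 31 of 83 called higher, 1 lower), mitochondrially encoded genes (0.516, 9 of 12 called higher), chaperones (0.173, 12 of 30 called higher, 1 lower) and endothelial markers (0.223, 4 of 30 called higher) completed the 18 called lists, 14 up and 4 down. With an estimated correlation these 5 had an adjusted p of 0.55, 0.7, 0.41, 0.55 and 0.72. The endothelial list kept its call in 7 of the 15 fits that left out 1 library, and its median was 0.121 without cortical WT replicate 6 and 0.141 without striatal WT replicate 5. Serine and glycine metabolism was not called (10 of 20 members called higher, 3 lower, median 0.273, adjusted p = 0.087). With an estimated correlation camera called 0 of the 31 lists (1 at an unadjusted p below 0.05), and fry called 19. Slc1a4 was not called between WT tissues (log2 fold change -0.09, SE 0.19, limma adjusted p = 0.71), and its value was 0.01 without striatal WT replicate 5.

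In KO mice 3129 genes were higher and 3322 lower in striatum than in cortex, of which 1049 and 896 differed at least 2-fold. The WT and KO comparisons share no libraries. Called in both were 2781 genes higher and 2977 genes lower in striatum, where independent lists of these sizes would share 778 and 852, and 0 of the genes called by limma in both went in opposite directions. Striatal projection neuron markers had 27 of 30 members called higher (median 2.49, camera adjusted p = 5.6e-15), cortical neuron markers had 19 of 25 members called lower and 2 called higher (median -1.70, camera adjusted p = 4.0e-08) and myelin genes had 28 of 30 members called higher (median 1.09, camera adjusted p = 1.1e-11). With an estimated correlation these 3 lists had an adjusted p of 0.46, 0.12 and 0.48. Cholesterol synthesis genes, 6 of 25 called lower and 2 higher, were not called as a list (median -0.0801, camera adjusted p = 0.25). At the preset correlation 16 of 31 lists were called, 12 up and 4 down, and with an estimated correlation 0 (2 at an unadjusted p below 0.05, smallest adjusted p = 0.12), while fry called 13. Slc1a4 did not differ by the test between KO tissues (log2 fold change -0.04, SE 0.20, limma adjusted p = 0.90). Without striatal KO replicate 4 it was 0.31 (limma adjusted p = 0.073), without that library and striatal WT replicate 5 it was 0.31 with a limma adjusted p of 0.026 (0.026 to 0.92 over the alternatives), and its direction also turned without cortical KO replicate 2 (0.03).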

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

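The tests of cortical tissue, of the share of projection neurons and of transcript length were chosen only after the results were seen; the other splits of the libraries and the test of chromosome 11 neighbours were planned before.

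A single library stood far from the other 3 of its group in 14 of 256 groups of 4 examined, where chance alone gives about 13. KO striatum, with 3 libraries, was not examined in this way, so the count does not speak for its libraries. Slc1a4 was 308 in KO cortex replicate 2 against 249 to 252 in the others, and Osmr was 409 in the same library against 119 to 153. In WT cortex, Cckar was 0.942 in replicate 5, the value of a single read, and listed at 0 in the others. In the same group Pmch was 25.1 in replicate 8 against 5.48 to 6.59, Camk2a was 117104 in replicate 7 against 89485 to 91074, and Gbx2 was 0 in replicate 7 against 1.88 to 2.01. In WT striatum, Lhx8 was 373 in replicate 6 against 285 to 297, Igfn1 was 55.7 in replicate 5 against 4.06 to 6.73, and Prlr was 2431 in replicate 5 against 341 to 661. The hypothalamic peptide genes Pmch and Hcrt were 7575 and 1152 in WT striatum replicate 8 against 35.3 to 993 and 20.5 to 141. Among list scores, the postsynaptic scaffold was 0.157 in WT striatum replicate 7 against -0.043 to -0.0121, myelin was -0.571 in WT cortex replicate 7 against 0.139 to 0.259, and circadian genes were 0.361 in WT cortex replicate 8 against -0.116 to -0.0772.

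The test of the difference between the knockout effects of striatum and cortex called Scube1 (1.86 on the log2 scale, striatum minus cortex) and, at the preset correlation, 13 lists. The median differences, with their range when 1 library was left out, were 0.529 (0.232 to 0.621) for cortical neuron markers, 0.229 (0.21 to 0.265) for cholesterol synthesis, -0.466 (-0.687 to -0.0962) for striatal neuron markers and -0.231 (-0.49 to 0.00883) for myelin genes. They were -0.135 (-0.225 to -0.0612) for microglia, -0.138 (-0.266 to -0.0625) for endothelial and -0.794 (-2.21 to 0.171) for choroid plexus markers. For circadian genes the value was -0.167 (-0.272 to -0.0757), for chaperones -0.0913 (-0.156 to -0.0302) and for chromosome 11 neighbours -0.0719 (-0.109 to -0.0526). It was -0.0764 (-0.129 to -0.0345) for ribosomal genes, -0.0788 (-0.156 to 0.0207) for respiratory subunits and -0.257 (-0.292 to -0.185) for mitochondrially encoded genes. None of these 13 lists held with an estimated correlation, where the smallest adjusted p was 0.26. With 1 library left out, the call was kept in each of 15 fits for cortical neuron, cholesterol, chromosome 11 and mitochondrially encoded genes, in 14 for circadian genes and microglia, and in 13 for striatal neuron, ribosomal and respiratory genes. It was kept in 11 for myelin genes, 10 for chaperones, 8 for choroid plexus and 7 for endothelial markers. The value nearest 0, or past it, came without striatal KO replicate 2 for cortical neuron markers, KO replicate 4 for striatal neuron markers and WT replicate 8 for circadian genes. It came without striatal KO replicate 3 for microglia, chaperones, myelin genes and respiratory subunits, and without cortical WT replicate 8 for ribosomal genes and WT replicate 6 for endothelial markers. Without striatal KO replicate 3 choroid plexus markers turned to 0.0159, and without striatal WT replicate 5 to 0.171.

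Other splits of the same libraries were counted for each comparison. In cortex 1 of 35 splits, the real one, called a gene (1, highest other 0), and that gene was the targeted Slc1a4. In WT striatum against cortex 1 of 35 called as many as 8601 (highest other 6). In KO striatum against cortex 1 of 35 called as many as 6451 (highest other 2645). No other split reached these 3 counts, and 1 of 35 is the smallest share that these splits can give. Chance was not excluded for the count of 13 genes in striatum, reached by 6 of 35 splits, the highest of which called 827. Nor was it for the count of 1 gene in the difference between tissues, reached by 10 of 100 drawn splits (highest other 2). These splits weigh counts and not single genes such as Slc1a4. The split with 827 genes set KO replicate 4 and WT replicates 5 and 8 against the rest, which points to a structure of the striatum libraries other than genotype. Chance was not excluded for any count of lists at the preset correlation. The 17 lists of cortex were reached by 2 of 35 splits (highest other 17), the 14 of striatum by 12 of 35 (highest other 18), the 13 of the difference by 33 of 100 (highest other 19), the 18 of WT tissues by 2 of 35 (highest other 20) and the 16 of KO tissues by 6 of 35 (highest other 20). The other splits called a median of 11 lists in cortex, 12 in striatum, 11 for the difference and 13 for either comparison of tissues. In each comparison 0 of them called no list. Calls at the preset correlation were therefore common with groupings other than the real ones.

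The rise of 12 genes in KO striatum was weighed against the make-up of the samples. For cortical tissue of the kind sampled here, 62 genes at least 10 times higher in WT cortex than in WT striatum, 5 of them among the 12, gave a median added cortex share of 6.2% (quartiles 3.14 and 13.8%, and 7.85%, 4.42% and 2.2% in the 3 KO libraries). A bootstrap over libraries gave 2.31 to 8.03%. Each WT striatum library, set against the other WT striatum libraries, gave -1.4 to 1.11%, below every KO library. The 62 genes were chosen for a low mean in WT striatum, which was also the baseline of the KO shares. The selection can therefore raise the KO shares, and part of this separation can be built in. The 12 need 13.9% (Neurod2) to 100%, with a median of 22.6%, but they were taken for their rise and 11 of the other 57 genes also reached 13.9%, so cortical tissue and other causes cannot be told apart with these values. A lower share of striatal projection neurons would raise the markers of the other cell types alike. The difference between the cortical neuron and microglia scores was 0.374 to 0.538 in KO and -0.641 to -0.0422 in WT striatum. The two-sided exact permutation p was 0.029, the smallest that these group sizes allow. These lists were paired after their directions were seen, and the cortical list holds Neurod2, so the test cannot decide. A lower share of these neurons, the differences between striatum libraries given above and an effect of the genotype all stay open. The genotype effect was not tested apart from the others.

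The lower ribosomal and respiratory lists were weighed against a trend with transcript length and GC content. With the trend removed, the ribosomal median in cortex went from -0.0722 to -0.00105 and its camera adjusted p from 5.2e-13 to 0.79. The change itself had gone (KO and WT scores overlapped already before, exact permutation p = 0.29). The trend could account for it, but the trend was fitted on genes that include these lists. A fall of short transcripts from another cause would then be removed as well. The respiratory median in cortex went from -0.117 to -0.0278, still called at the preset correlation (camera adjusted p = 5.2e-07) though not with an estimated one (adjusted p = 0.55). KO and WT scores lay apart (exact permutation p = 0.029, and 0.057 before). So small a remainder after a smooth fit cannot tell the trend from other causes. In striatum the ribosomal median went from -0.156 to -0.0622 and the respiratory median from -0.185 to -0.104. Both were still called at the preset correlation but not with an estimated one (camera adjusted p of 0.61 and 0.5). KO and WT scores overlapped before (exact permutation p of 0.086 and 0.20) as after (0.20 and 0.26), so the trend and other causes cannot be told apart there with this spread. An effect of the genotype on these genes stays open and was not tested apart from the trend.

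Genes near Slc1a4 on chromosome 11 could carry strain variants kept with the targeted locus. Of 34 neighbours tested, 0 were called by limma in either tissue, against 12 of 16995 other genes (one-sided Fisher's exact test, p = 1), and 9 in striatum (26.5%, against 15.2% of the other genes) and 0 in cortex had an unadjusted p below 0.05. With 12 calls elsewhere, 0.024 called neighbours would be expected by chance, so a count of 0 lies too near that value to decide, although it met the bound set beforehand. Variants next to the locus therefore cannot be told apart from their absence with these calls.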

How the results depend on the processing

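The fits without the choroid-rich striatum libraries (KO replicate 4 and WT replicate 5) those with length and GC trends removed, and the list tests with each library left out were chosen only after the results were seen. Depth was not the main limit on average for genes with at least 20 summed reads. Replicates differed there by a mean chi-square per gene of 7.12 to 77.4, far above counting noise. That mean does not speak for genes with few reads. The fall of Slc1a4 in cortex stayed called in 15 of 15 alternatives (-2.64 to -2.60) and with each library left out (-2.69 to -2.56). In striatum it stayed called in 14 of 15 (-2.61 to -2.31) and with each library left out (-2.77 to -2.21); on striatum libraries alone it was -2.56 with an adjusted p of 0.088 (2.8e-32 to 0.088 over the alternatives), with fewer residual degrees of freedom.

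The number of genes called in cortex was 3 with DESeq2, 2 with sample weights, 1 on cortex libraries alone and 1 with each library left out. In striatum it was 22 with no filter, 333 with DESeq2 (174 higher, 159 lower), 3 with voom, 35 with sample weights, 0 on striatum libraries alone (limma, 1140 at an unadjusted p below 0.05), 344 without the choroid-rich libraries and 4 to 517 with a library left out (517 without KO replicate 4, 187 without WT replicate 8). DESeq2 also made the most false calls on simulated striatum data, 38 of 218. That simulation gave both tissues the same spread, so it does not show the rate in the real striatum libraries. For the difference between tissues it was 15 with DESeq2, 4 with sample weights, 0 with the replicate number as a fixed block (limma, 868 at an unadjusted p below 0.05), 19 without the choroid-rich libraries and 1 to 8 with a library left out. Counts for striatum against cortex stayed within 1.5 times, at 7564 to 9241 in WT and 5413 to 6769 in KO with a library left out. Replicate numbers are shared between tissues, the correlation of same-numbered libraries was 0.0037 to 0.14 (above 0.1 in 2 of 7 pairs), and 5 of 7 striatum libraries matched their own number best; with the number as a random effect the counts were 1 in cortex and 13 in striatum. Camera with an estimated correlation called 0 lists in each of the 5 comparisons (smallest adjusted p = 0.12); fry called 0 in cortex, 3 in striatum and 0 for the difference. With a library left out the preset correlation called 13 to 17 lists in cortex, 12 to 18 in striatum and 7 to 16 for the difference.

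Directions of called lists turned with a library left out for astrocyte (-0.108 to 0.0052) and microglia markers (-0.0741 to 0.012) in cortex, for myelin genes in striatum (-0.472 to 0.0404), and for choroid plexus markers (-2.21 to 0.171), myelin genes (-0.49 to 0.00883) and respiratory subunits (-0.156 to 0.0207) in the difference between tissues. The named genes whose direction turned were not called with all libraries. ND4 in striatum was 0.0113 with quantile normalization (adjusted p = 0.97, range 0.025 to 0.97). Slc1a4 between WT tissues was 0.00819 without the choroid-rich libraries (-0.152 to 0.00819 with a library left out). Between KO tissues it was 0.0354 with edgeR, 0.0322 with DESeq2, 0.248 with sample weights, 0.309 without the choroid-rich libraries and -0.251 to 0.309 with a library left out. For the difference between tissues it was -0.0146 with quantile normalization and -0.16 to 0.4 with a library left out. Over the alternatives other than leaving out 1 library, the named genes of striatum lost their call in 25 cases and gained one in 17, and those of cortex gained one in 3. Except where fewer samples were fitted, the cause was not tested.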
